A study of Arabidopsis thaliana with 12 samples.

How the data were processed

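Poly(A) RNA from Arabidopsis thaliana seedlings, 10 days old, was sequenced in 12 libraries, 3 for each of 4 groups: WT control, WT dehydrated, cost1 control and cost1 dehydrated. Per the labels, seedlings stood upright on plates of medium, and those of similar size were dehydrated on a petri dish for 6 h. Nothing in the labels states that the 3 libraries of a group came from separately grown plants or separate dishes, so the p-values measure the spread between these samples, which may be technical.

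Per the submitters' processing notes, STAR 2.4.0, HTSeq 0.6.0 and DESeq2 were used with the TAIR10 genome; which step each served, and its options, is not given in the sources used here. Per the file headers, each library has a deposited table with the gene, its transcripts, a length in bases, an expected count and an FPKM. The deposited expected count is an estimate of the reads of a gene before any scaling: 8.57% of the listed values lay more than 0.005 from a whole number, and these held 20.25% of the summed counts. The deposited FPKM values are, by their header, scaled to transcript length and to sequencing depth by the authors; the exact formula is not given in the sources used here. The columns have the layout that RSEM writes, but no source names that program. The tables name 6 transcripts of AT1G01020, more than the TAIR10 models of that gene, so the annotation counted is not settled. The deposited read statistics give, for each library, read numbers and base and quality percentages before and after the authors discarded reads for unknown bases, low quality or adapter; the tool is not given in the sources used here.

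Genes at 0 were not listed, and an absent gene was read as 0. Of 32737 such absences among genes listed elsewhere, 98.37% had the other libraries of the group averaging under 5 counts, and the highest average was 152. The tables listed 24035 genes in at least 1 library and 18910 in all 12. Names came from a TAIR10.1 annotation, which matched 23831 of the 24035 loci; the 204 unmatched loci were all organellar. The files give no coordinates and name TAIR10, so no coordinates are given.

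Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr over the groups, which left 18809, libraries were scaled by TMM, and quasi-likelihood F tests were run in 1 fit of all 12 libraries with a coefficient for each group and 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, within each comparison, and a gene was called at an adjusted p under 0.05. The 5 comparisons were the dehydration response in WT and in cost1, the genotype difference in control and under dehydration, and the interaction, the response in cost1 minus that in WT. Errors of log2 changes are standard errors from the F statistic, and values by group are means with the SD in CPM at TMM scaling. Against a group with a count of 0 a fold is a lower bound from a floor of 3 counts over the group; with 1 to 3 counts the ratio is given with a 95% Poisson interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

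The design, the comparisons, the tests, the alternatives and 26 gene lists of 428 loci were fixed before the data were examined. The lists were dehydration- and ABA-induced genes, ABA receptors, clade A PP2C phosphatases, ABA kinases and bZIP factors, ABA synthesis and catabolism, DREB and CBF factors, autophagy genes, proline and raffinose metabolism, photosynthesis nuclear genes, expansins and xyloglucan endotransglucosylases, aquaporins, brassinosteroid synthesis and signalling, auxin response genes, jasmonate genes, salicylate and defence genes, senescence and dark-induced genes, heat shock genes, unfolded protein response genes, cell cycle and DNA replication genes, nitrate uptake and assimilation, glucosinolate synthesis, flavonoid and anthocyanin synthesis, circadian clock genes, root cell markers, stomatal lineage and guard cell markers, and seed storage and embryo markers. In the annotation 410 of the loci carried the symbol of the list, 7 another symbol of the gene and 11 none; 4 loci were listed in no library. Each list was tested with camera from limma 3.58.1 at the preset correlation of 0.01 and again with an estimated correlation, and with fry for a change on balance in 1 direction, adjusted over the 26 lists. Counts of called members are given over all genes tested and adjusted over the list alone.

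Named genes followed a fixed rule: COST1; for each comparison the 6 largest rises and falls among called genes whose libraries did not overlap between the groups and whose higher group averaged at least 5 FPKM, or all genes of a comparison with fewer; up to 4 members of each list with the smallest p; and genes called the same way in the genotype difference in control and the WT response. CYP86A1 fell outside the 5 FPKM limit and was named because it was 1 of 7 called genes, after its values were seen. Lists of suberin, dawn-phased, evening-phased and root-only genes were added after the data were seen and are used in the closing part only.

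The tests were tried on simulated data for the genotype difference in control: negative binomial counts of 18809 genes were drawn with the WT group means in both genotypes and the fitted dispersions. Of genes averaging at least 5 CPM, 100 were changed 2-fold and 100 were changed 4-fold. The edgeR test recovered 62 of the 100 at 2-fold and 92 of the 100 at 4-fold, with 12 unchanged genes called; DESeq2 recovered 76 and 94 with 34 unchanged genes called, and limma-voom 62 and 92 with 15. A planted list of 30 genes at 1.5-fold gave an adjusted p of 4.8e-24 at the preset correlation and of 6.32e-05 with an estimated correlation, and 0 of 26 unplanted lists were called by either. Genes were drawn independently, so the simulation does not show how the list tests behave where members of a list vary together. The many planted changes ease the adjusted p, so the shares recovered do not give the power where few genes differ.

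The genotype difference in control and the WT dehydration response share the WT control libraries. Their covariance across genes was therefore set against 20 simulations with neither a genotype effect nor a dehydration response, in which genes were drawn independently. These were run with all libraries and, added after the data were seen, without cost1 control replicate 2. The covariance with the mean of both dehydration responses, which that sharing does not inflate in the simulations, was computed beside it. The alternatives were DESeq2 1.42.0 and limma-voom on the same counts, median-ratio factors, no scaling beyond the total, organellar loci left out, no filter, a filter of at least 10 CPM in at least 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of the compared groups only, the replicate number as a block, an added limit of 2-fold, and each library left out in turn. The labels give each group replicates 1, 2 and 3 without saying what a number shares. Deviations from the group means correlated at 0.1714, 0.381 and 0.1775 between same-numbered control and dehydrated cost1 libraries, so these were taken as paired, from the data alone. The pairing is not established: differently numbered pairs of that comparison reached 0.1644 and 0.1396. WT dehydrated replicate 2 and cost1 dehydrated replicate 3 reached 0.3907. The block was a term over all 12 libraries. Leaving out libraries was added for the list tests after the data were seen. Other groupings of the libraries were 10 splits for each comparison of 3 libraries against 3, and for the interaction 100 groupings by labels moved within treatment, with 10 that keep each number's libraries together. No library and no column of values needed for these comparisons was left out.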

Results

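The 12 libraries measured gene expression in WT and cost1 seedlings, with and without 6 h of dehydration, 3 libraries per group. The series sets out to compare how the mutant and the wild type respond to drought, and its title links COST1 to the attenuation of autophagy. Clean reads, 49 bases long, numbered 12320257 to 13028160 per library. The expected counts summed to 5884728 to 6223687, or 45.8% to 47.8% of the clean reads. Between 21003 and 21556 genes were listed in a library, and the 10 most abundant genes held 3.76% to 7.54% of the counts. Chloroplast loci held 0.0116% to 0.0593% of the counts and mitochondrial loci 0.0032% to 0.0095%.

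COST1 (AT2G45260), a gene of the DUF641 family that the mutant is named for, was lower in every cost1 library than in every WT library. Its expected count was 191 ± 23.0 (SD, n = 3) in WT control, 163 ± 23.57 in WT dehydrated, 44.3 ± 7.24 in cost1 control and 58.2 ± 3.00 in cost1 dehydrated. The difference was −2.10 on the log2 scale in control (SE 0.17, adjusted p = 0.000683) and −1.48 under dehydration (SE 0.17, adjusted p = 0.011). The call under dehydration was lost without WT dehydrated replicate 1 (adjusted p = 0.111), WT dehydrated replicate 2 (0.0807) or cost1 dehydrated replicate 3 (0.0734), with a range of 3.26e-09 to 0.111 over 17 alternatives. In control it held in all 17 (3.79e-19 to 0.00739). Where a left-out library cost the call under dehydration, the difference was −1.38 to −1.54. A fit of the dehydrated libraries alone, which is not among the 17, did not call COST1 under dehydration either. The counts left in the mutant include fractions; whether they are reads shared with related genes or remaining transcript is not shown by these tables, nor is the part of the gene they cover.

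**Figure D1:**
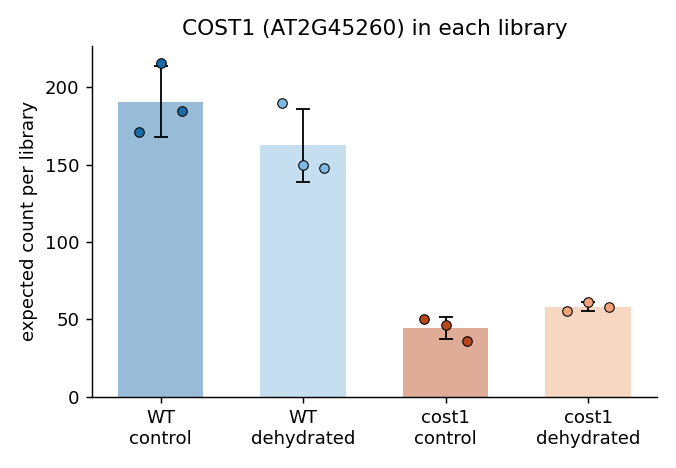
Expected count of COST1 per library (y axis) in the 4 groups (x axis). Bars are means, error bars the SD of 3 libraries and points the single libraries; the cost1 libraries lie between 36.2 and 61.2 and the WT libraries between 148 and 216.

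Treatment separated the libraries on the 1st principal component, which held 77.4% of the variance of log2 CPM. Cost1 control replicate 2 lay at −50.4 on it, away from the other control libraries at −91.1 to −86.7, and cost1 dehydrated replicate 2 lay farthest among the dehydrated ones at 114. Across genes, which are not independent replicates, cost1 control replicate 2 correlated at 0.945 and 0.951 with the others of its group, while those correlated at 0.983 with each other.

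**Figure D2:**
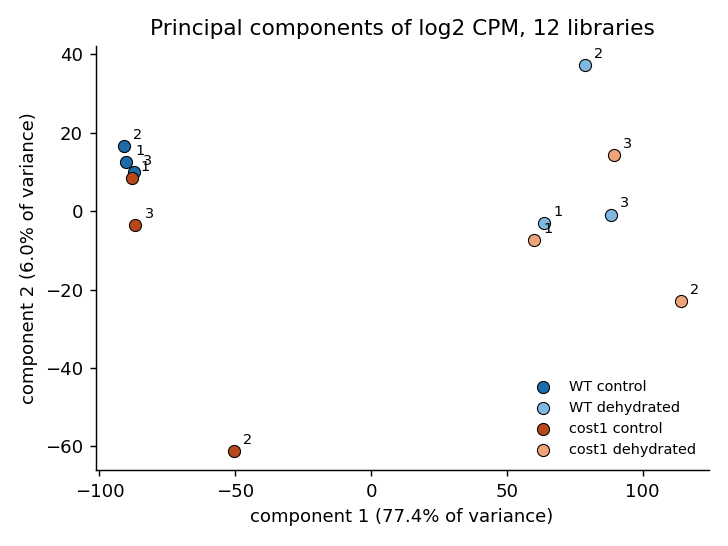
Principal components 1 (x axis, 77.4% of the variance) and 2 (y axis, 5.99%) of log2 CPM in 12 libraries, coloured by group and numbered by replicate. Control and dehydrated libraries lie on opposite sides, with cost1 control replicate 2 at −50.4 and −61.2.

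The WT dehydration response asked which genes 6 h of water loss moved in the wild type. Of the dehydration- and ABA-induced genes 23 of 24 measured members rose (23 adjusted over the list alone) and 1 was not called, with a median log2 change of 5.85 (adjusted p = 1.17e-21). The list had adjusted p = 0.131 with an estimated correlation. RD29A rose by 7.19 (SE 0.49), and ERD10, which encodes a dehydrin, by 4.65 (SE 0.27). SAUR63, an auxin-induced gene, fell from 8.87 ± 1.43 to 0.0584 ± 0.101 CPM. In all, 4680 genes were higher and 3869 lower of 18809 tested.

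The abscisic acid (ABA) pathway moved at several steps in WT. NCED3, which makes a committed step of ABA synthesis, rose by 7.56 (SE 0.54) and CYP707A1, which breaks ABA down, by 3.19 (SE 0.40). Of ABA synthesis and catabolism 9 of 11 members rose (9 adjusted over the list alone) and 2 were not called, with a list test at adjusted p = 0.000477 and adjusted p = 0.224 with an estimated correlation. All 8 clade A PP2C phosphatases, which hold the pathway back, rose (8 adjusted over the list alone), ABI1 by 4.13 and PP2CA by 3.95. The median was 4.57, or 4.04 with a gene at 0 in control set at its bound (adjusted p = 3.75e-09, and adjusted p = 0.131 with an estimated correlation). ABA receptors went both ways. PYL7 rose by 3.23 and PYL9 by 2.45, while 7 of 9 fell (2 up and 7 down adjusted over the list alone), PYL6 by 6.36 and PYL4 by 4.54 (adjusted p = 0.0414, and adjusted p = 0.329 with an estimated correlation). Without WT dehydrated replicates 1, 2 or 3 the receptor list was not called (adjusted p = 0.0797, 0.0924 and 0.103), nor without scaling beyond the total (median −1.65, adjusted p = 0.0788). Among ABA kinases and bZIP factors 5 of 8 rose (5 adjusted over the list alone) and 3 were not called, with ABF3 up by 3.33 and OST1 by 1.03 (adjusted p = 0.0115, and adjusted p = 0.184 with an estimated correlation). All 5 DREB and CBF factors rose (5 adjusted over the list alone), DREB2A by 4.94 (adjusted p = 0.000477, and adjusted p = 0.131 with an estimated correlation).

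Autophagy genes rose in part: 22 of 44 measured members rose and 22 were not called (22 and 0 down adjusted over the list alone), with a median of 0.39. ATG8H, of the ATG8 family that coats autophagosomes, rose by 2.22 (SE 0.36) and ATG12A by 1.36 (SE 0.21). The list was called at adjusted p = 0.0292, with adjusted p = 0.58 with an estimated correlation, and was not called without WT dehydrated replicate 2 (adjusted p = 0.0598) or cost1 control replicate 2 (adjusted p = 0.0542), nor without scaling beyond the total (adjusted p = 0.0605).

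A further 7 lists passed the test upward in WT. Among jasmonate genes 18 of 19 rose (18 adjusted over the list alone) with a median of 3.51, the repressor JAZ1 by 5.17 and the synthesis gene OPR3 by 3.28 (adjusted p = 2.16e-13, and adjusted p = 0.14 with an estimated correlation). In proline and raffinose metabolism 8 of 11 rose and 1 fell (8 and 1 adjusted over the list alone), GOLS1, for galactinol synthesis, by 3.52 (adjusted p = 0.000704, and adjusted p = 0.131 with an estimated correlation). Aquaporins went both ways, 11 of 18 up and 3 down (11 and 3 adjusted over the list alone), with PIP2;3 up by 5.58 and TIP2;2 by 2.97 (adjusted p = 0.000152, and adjusted p = 0.14 with an estimated correlation). Senescence and dark-induced genes had 10 of 15 up and 1 down (10 and 1 adjusted over the list alone), the transcription factor NAP up by 3.69 (adjusted p = 0.00267, and adjusted p = 0.131 with an estimated correlation). Heat shock genes had 6 of 9 up (8 adjusted over the list alone), HSFA2 by 4.39 (adjusted p = 0.00609, and adjusted p = 0.243 with an estimated correlation). Salicylate and defence genes had 7 of 20 up (7 adjusted over the list alone), PAD3, for camalexin synthesis, by 6.99 (adjusted p = 0.0113, and adjusted p = 0.502 with an estimated correlation). Flavonoid and anthocyanin synthesis had 9 of 15 up (12 adjusted over the list alone), the regulator PAP1 by 6.41 (adjusted p = 0.0179, and adjusted p = 0.58 with an estimated correlation).

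A further 4 lists passed the test downward in WT. Of cell cycle and DNA replication genes 11 of 23 fell and 0 rose (12 down adjusted over the list alone), MCM5 by 1.47 and PCNA1 by 1.63 (adjusted p = 0.000551, and adjusted p = 0.309 with an estimated correlation). Auxin response genes had 9 of 16 down and 3 up (9 and 3 adjusted over the list alone), with PIN3 at −1.20 (adjusted p = 0.000704, and adjusted p = 0.131 with an estimated correlation). In nitrate uptake and assimilation 7 of 11 fell and 1 rose (7 and 1 adjusted over the list alone), the nitrite reductase NIR1 at −1.90 (adjusted p = 0.00267, and adjusted p = 0.131 with an estimated correlation). Of photosynthesis nuclear genes 5 of 29 fell and LHCB4.3 rose (3 down and 1 up adjusted over the list alone). The median was −0.48 and the list was called at adjusted p = 0.0121, with adjusted p = 0.613 with an estimated correlation and adjusted p = 0.0854 without WT dehydrated replicate 3.

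The other 8 lists were not called in WT, although some members moved. Expansins and xyloglucan endotransglucosylases had 4 of 17 up, XTH18 by 4.51, and 8 down (4 and 8 adjusted over the list alone, adjusted p = 0.119), and were called without cost1 dehydrated replicate 1 (0.0373). Brassinosteroid synthesis and signalling had 1 of 12 up and 5 down (1 and 5 adjusted over the list alone, adjusted p = 0.119), the receptor BRI1 at −1.79. Glucosinolate synthesis had 3 of 13 up and 4 down (3 and 4 adjusted over the list alone, adjusted p = 0.578). The unfolded protein response genes had 3 of 10 up, BZIP60 by 2.78, and 2 down (3 and 3 adjusted over the list alone, adjusted p = 0.237). Circadian clock genes had 1 of 16 up, BOA by 1.18 (1 adjusted over the list alone, adjusted p = 0.892). Stomatal lineage and guard cell markers had 1 of 11 up and 6 down (1 and 6 adjusted over the list alone, adjusted p = 0.112). Root cell markers had WOX5 up by 4.27 and 3 of 4 down (1 and 3 adjusted over the list alone, adjusted p = 0.139). Their median was −0.74 and their mean 0.02; in 14 of 130 list results median, mean and test differed in sign, and 0 of these were called. The median of seed storage and embryo markers was 1.66, or 1.15 with a gene at 0 set at its bound, with EM1 and EM6 of 4 up (2 adjusted over the list alone, adjusted p = 0.593). By fry, which asks whether a list moves on balance and compares it with no other genes, 21 lists passed in WT, 17 of the 18 above among them. Photosynthesis nuclear genes did not (adjusted p = 0.112). Brassinosteroid (0.00504), root cell (0.00274), stomatal (0.0109) and unfolded protein response (0.0161) lists passed by fry alone.

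The largest single rises in WT, ranked by the fitted log2 change under the naming rule, were mostly from no reads. Their folds are lower bounds, which do not rank them against genes with reads in control. AT5G05220 was at least 350-fold higher, BGLU27, a beta-glucosidase gene, at least 300-fold, AT5G53710 at least 208-fold, the transcription factor gene MYB102 at least 165-fold and AT1G25150 at least 131-fold. PUB19, a ubiquitin ligase gene, went from 0.259 ± 0.0878 to 465 ± 74.1 CPM. Among falls, AT4G38820 was at least 24.2-fold and AT4G34790 at least 22.1-fold lower, SAUR63 154-fold (27.3 to 6134) and AT1G29430 133-fold (23.4 to 5273) by their counting intervals, and FTM1 and PYL6 changed by −6.44 and −6.36. The directions are relative to TMM scaling: without scaling beyond the total the median of all genes shifted by −0.147 and 42.8% of the called genes were higher, against 54.7%. Of the called genes, 2946 rose and 1517 fell at least 2-fold.

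The same treatment in cost1 moved 4974 genes up and 4611 down. All 24 dehydration- and ABA-induced genes rose (24 adjusted over the list alone), with a median of 5.28, RD29A by 6.28 (SE 0.47) and ERD10 by 4.69 (SE 0.27). The list was called at adjusted p = 4.83e-20, with adjusted p = 0.173 with an estimated correlation. Of autophagy genes 31 of 44 rose and 13 were not called (31 adjusted over the list alone), with a median of 0.56, ATG8H by 2.96 (SE 0.37), ATG18F by 1.82 (SE 0.17) and ATG9 by 1.12 (SE 0.16). The list was called at adjusted p = 0.000268, with adjusted p = 0.373 with an estimated correlation. COST1 itself was higher after dehydration in the mutant by 0.53 (SE 0.18, adjusted p = 0.0282). That call was lost without cost1 control replicate 3 (adjusted p = 0.118), cost1 dehydrated replicate 2 (0.0907) or cost1 dehydrated replicate 3 (0.0541), without scaling beyond the total (0.0959) and on log2(FPKM + 0.1) (0.0727), in a range of 0.0253 to 0.118. The interaction of COST1 was 0.62 (SE 0.24, adjusted p = 0.999).

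Further lists passed the test upward in cost1. All 8 clade A PP2C phosphatases rose (8 adjusted over the list alone), with ABI1 up by 4.07 (adjusted p = 3.7e-08), and so did all 5 DREB and CBF factors (5 adjusted over the list alone, adjusted p = 0.000524), with adjusted p = 0.173 with an estimated correlation for both. Jasmonate genes had 18 of 19 up (18 adjusted over the list alone, adjusted p = 1.16e-09), and senescence and dark-induced genes 12 of 15 up and 1 down (12 and 1 adjusted over the list alone, adjusted p = 0.000116), with NAP up by 4.37. Both had adjusted p = 0.173 with an estimated correlation. Aquaporins had 11 of 18 up and 4 down (11 and 4 adjusted over the list alone, adjusted p = 0.000258), proline and raffinose metabolism 8 of 11 up and 1 down (8 and 1 adjusted over the list alone, adjusted p = 0.00104) and ABA kinases and bZIP factors 5 of 8 up (5 adjusted over the list alone, adjusted p = 0.00366). Each had adjusted p = 0.173 with an estimated correlation. Of ABA synthesis and catabolism 9 of 11 rose (9 adjusted over the list alone, adjusted p = 0.00104), NCED3 by 6.79, and of heat shock genes 6 of 9 (6 adjusted over the list alone, adjusted p = 0.0111), with adjusted p = 0.259 with an estimated correlation for both. Salicylate and defence genes had 8 of 20 up (8 adjusted over the list alone, adjusted p = 0.00248, and adjusted p = 0.381 with an estimated correlation).

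Cell cycle and DNA replication genes had 16 of 23 down in cost1 and 0 up (18 down adjusted over the list alone, adjusted p = 2.22e-06), PCNA1 at −1.93. Auxin response genes had 9 of 16 down and 3 up (9 and 3 adjusted over the list alone, adjusted p = 0.00366), and nitrate uptake and assimilation 7 of 11 down and 1 up (10 and 1 adjusted over the list alone, adjusted p = 0.0111). Each of these lists had adjusted p = 0.173 with an estimated correlation. Photosynthesis nuclear genes had 16 of 29 down and 0 up (16 down adjusted over the list alone), with a median of −0.79 (adjusted p = 0.00104, and adjusted p = 0.493 with an estimated correlation). Stomatal lineage and guard cell markers had 6 of 11 down (6 adjusted over the list alone, adjusted p = 0.0499, and adjusted p = 0.307 with an estimated correlation), a call lost without scaling beyond the total (0.0726) and without WT dehydrated replicate 2 (0.0549), cost1 control replicate 3 (0.065), cost1 dehydrated replicate 2 (0.0657) or cost1 dehydrated replicate 3 (0.0719). The other 9 lists were not called. Among them flavonoid and anthocyanin synthesis, with 3 of 15 up (2 adjusted over the list alone, adjusted p = 0.25), was called without cost1 control replicate 2 (median 3.62, adjusted p = 0.00757), the library that lay apart, and so were ABA receptors (median −1.43, adjusted p = 0.00291) and brassinosteroid synthesis and signalling (median −0.46, adjusted p = 0.0305). Expansins and xyloglucan endotransglucosylases were called without cost1 dehydrated replicate 1 (0.012), root cell markers without WT dehydrated replicate 3 (0.0459), and glucosinolate synthesis without WT dehydrated replicate 1 (0.031), cost1 control replicate 1 (0.0298), cost1 control replicate 3 (0.0465) or cost1 dehydrated replicate 1 (0.0232). Under the replicate block, in the 1 comparison whose numbers were taken as paired, glucosinolate synthesis (−1.49, adjusted p = 0.0387), the expansin list (−1.42, 0.0461) and PAP1 (2.48, 0.0471) were called in cost1. PAP1 moved with the setting, and was also called on log2(FPKM + 0.1) (4.35, 0.022) and without cost1 control replicate 2 (6.56, 0.000258). By fry 24 lists passed, all 17 above among them. The 7 by fry alone were ABA receptors (0.0276), the expansin list (0.0156), brassinosteroid (0.00446), unfolded protein response (0.00446), clock (0.0462), root cell (0.000656) and seed (0.0462) lists.

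The largest rises in cost1 by the same ranking were again of AT5G05220, 1602-fold by its counts (interval 287 to 63321), AT5G53710, 725-fold (130 to 28695), AT1G25150, at least 89.9-fold, and CYP715A1, a cytochrome P450 gene, at least 77.9-fold, with AT4G28140 up by 8.90 and AT4G33467 by 8.88. The lower bounds of AT1G25150 and CYP715A1 do not show that they rose more than genes with reads in control. The largest falls were of MEE3, 67.9-fold (11.8 to 2718), SAUR63, 58.4-fold (15.8 to 488), AT4G34770, 36.7-fold (9.83 to 308), PYL6 at −5.35, CRK30, a receptor-like kinase gene, at −5.10 and FLA9, an arabinogalactan protein gene, at −4.87. Of the called genes, 4105 were higher in both genotypes, 3144 lower in both and 1 opposite, against 1238 and 948 for independent lists, so that 66.6% of the genes called in either were called in both. Across genes, which are not independent replicates, the log2 changes of the responses correlated at 0.936. Without scaling beyond the total the median shifted by −0.152 and 40.9% of the called genes were higher, against 51.9%.

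**Figure D3:**
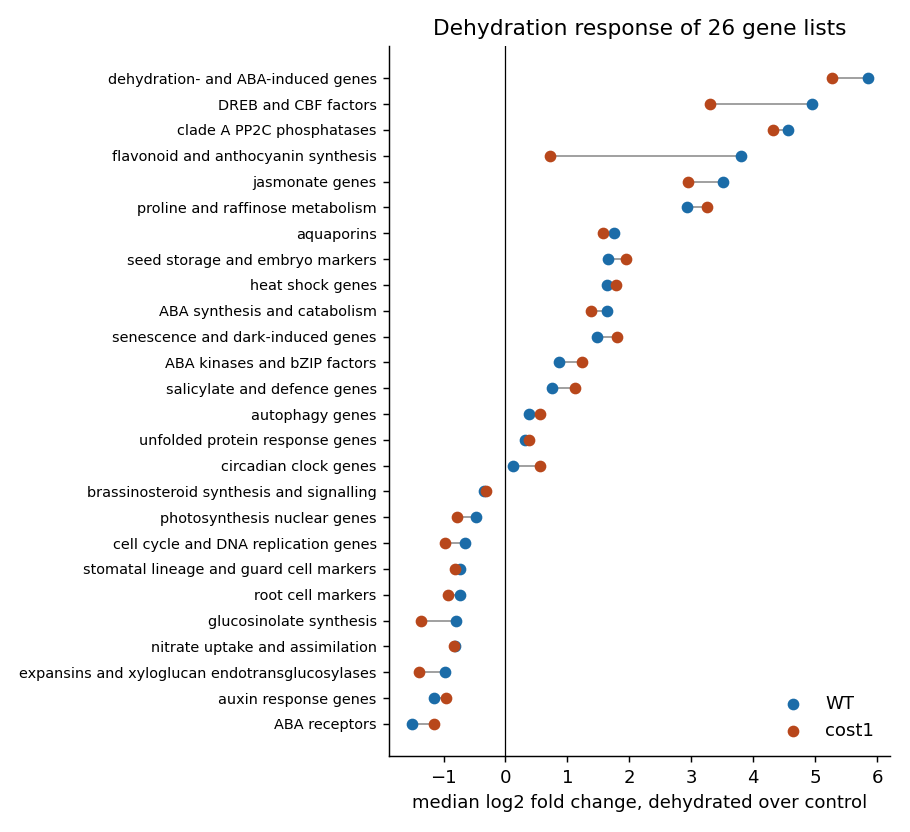
Median log2 fold change after dehydration (x axis) of the measured genes of each of 26 lists (y axis), in WT and in cost1, as fitted. The dehydration- and ABA-induced genes lie at 5.85 and 5.28, and circadian clock genes at 0.12 in WT turn to −0.02 without scaling beyond the total.

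The genotype difference in control asked how cost1 differed from WT without the treatment. The libraries cover WT and cost1 only, so an effect of the mutation cannot be told apart from another difference between the lines. Besides COST1, 3 genes differed, each higher in all 3 cost1 libraries than in all 3 WT libraries; chance gives no overlap for 10% of genes. AT1G75945 was at 6.61 ± 1.46 CPM in cost1 control and 0.106 ± 0.0915 in WT control, 63.7-fold by counts (interval 17.3 to 532, adjusted p = 0.00872). AT1G64795 was at 2.86 ± 0.335 CPM in cost1 and had a count of 0 in WT, at least 18.3-fold higher (adjusted p = 0.021). AT4G38080, annotated as a hydroxyproline-rich glycoprotein family gene, differed by 2.31 (SE 0.30, adjusted p = 0.027), with an interaction of −0.91 (SE 0.41, adjusted p = 0.999). Over 17 alternatives the adjusted p of AT1G64795 ranged from 0.000528 to 0.108, that of AT1G75945 from 0.000277 to 0.1 and that of AT4G38080 from 6.94e-06 to 0.29. The calls were lost easily while the fold moved little: AT4G38080 was at 2.12 to 2.55 where it was not called. Only COST1 stayed called in each of the alternatives; the count was 1 without any of the WT control replicates 1, 2 and 3 or cost1 control replicate 3, 2 without cost1 control replicate 2, cost1 dehydrated replicate 1 or cost1 dehydrated replicate 3, and 7 without cost1 control replicate 1. By DESeq2 15 genes were called and by limma-voom 3, and 893 genes had an unadjusted p under 0.05, against 940 by chance.

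Gene lists between the genotypes in control changed with single libraries. No member was called in any of the 5 lists that passed the test, each with adjusted p = 0.817 with an estimated correlation. Flavonoid and anthocyanin synthesis had positive changes in 15 of 15 genes with a median of 2.05 (7 higher adjusted over the list alone, adjusted p = 2.18e-09), or 0.46 without cost1 control replicate 2 (adjusted p = 0.00667). Dehydration- and ABA-induced genes had positive changes in 19 of 24 with a median of 0.78 (0 adjusted over the list alone, adjusted p = 0.000256), or 0.17 without cost1 control replicate 2 (adjusted p = 0.174). Clade A PP2C phosphatases had a median of 0.65, or 0.51 with a gene at 0 set at its bound (0 adjusted over the list alone, adjusted p = 0.00231), and 0.13 without cost1 control replicate 2 (adjusted p = 0.539). Jasmonate genes had a median of 0.44 (0 adjusted over the list alone, adjusted p = 0.0188), −0.04 without cost1 control replicate 2 (adjusted p = 0.918) and 0.35 without WT control replicate 2 (adjusted p = 0.135). Seed storage and embryo markers had a median of 2.98, or 1.74 with a gene at 0 set at its bound and 1 gene at the floor left out (1 higher adjusted over the list alone, adjusted p = 0.0188), and 1.05 without cost1 control replicate 3 (adjusted p = 0.237). Autophagy genes were not called (median −0.04, adjusted p = 0.168). Salicylate and defence genes were not called either (median 0.22, adjusted p = 0.41), but were called without WT control replicate 3 (0.57, 0.00998), cost1 control replicate 3 (0.44, 0.0103) and, the other way, cost1 control replicate 2 (−0.36, 0.00667). Other lists were called only with a library left out. ABA synthesis and catabolism was called without WT control replicate 1 (0.0174) or cost1 control replicate 3 (0.00875). Photosynthesis nuclear genes were called without either of these (0.0174 and 0.00875) or cost1 control replicate 1 (0.0402). Unfolded protein response genes were called without WT control replicate 3 (0.00998). ABA receptors (0.0469), nitrate uptake and assimilation (0.0437) and glucosinolate synthesis (0.0402) were called without cost1 control replicate 1. Lists called without 1 library numbered 3 (cost1 control replicate 2) to 9 (cost1 control replicate 1). By fry no list passed in this comparison (lowest adjusted p = 0.847).

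The genotype difference under dehydration asked how the mutant differed after 6 h of water loss. Of 7 called genes, COST1 was lower and 6 were higher, and AT1G64795 and AT1G75945 were called in control too. AT1G64795 was 90.8-fold higher by counts (interval 15.9 to 3627, adjusted p = 0.011) and AT1G75945 at least 19.5-fold (adjusted p = 0.0184). AT5G24240, annotated as a phosphatidylinositol 4-kinase gamma-like gene, was at 12.8 ± 2.05 CPM in cost1 and 0.923 ± 0.736 in WT (log2 3.77, SE 0.49, adjusted p = 0.0197). PELPK1, a cell wall glycoprotein gene, differed by 2.52 (SE 0.29, adjusted p = 0.011). CYP86A1, which oxidises fatty acids for suberin, was at 8.42 ± 3.097 CPM in cost1 and 1.21 ± 0.476 in WT (log2 2.78, SE 0.38, adjusted p = 0.027). AT5G37600 (GSR 1), a cytosolic glutamine synthetase gene, differed by 0.90 (SE 0.12, adjusted p = 0.027). The interaction was −0.34 for AT5G24240, 0.77 for PELPK1, 0.65 for CYP86A1 and 0.24 for GSR 1, each with an adjusted p of at least 0.999.

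These calls too were lost easily while the folds moved little. Where it was not called AT5G24240 was at 3.38 to 3.84, PELPK1 at 2.39 to 2.64, CYP86A1 at 2.44 to 2.93 and GSR 1 at 0.82 to 0.90. GSR 1 and CYP86A1 lost the call even without WT control replicates 1, 2 or 3, which are not in the comparison (GSR 1 0.0647, 0.0811 and 0.0856, CYP86A1 0.0621, 0.0645 and 0.0651). The count was 0 without WT dehydrated replicate 1, WT dehydrated replicate 2 or cost1 dehydrated replicate 3, and 4 without cost1 control replicate 3 or cost1 dehydrated replicate 2. The highest adjusted p over 17 alternatives was 0.111 for AT1G64795 and AT1G75945, 0.119 for PELPK1 and 0.25 for AT5G24240, CYP86A1 and GSR 1. A fit of the dehydrated libraries alone called 0 genes, DESeq2 29 and limma-voom 6, and 1637 genes had an unadjusted p under 0.05.

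**Figure D4:**
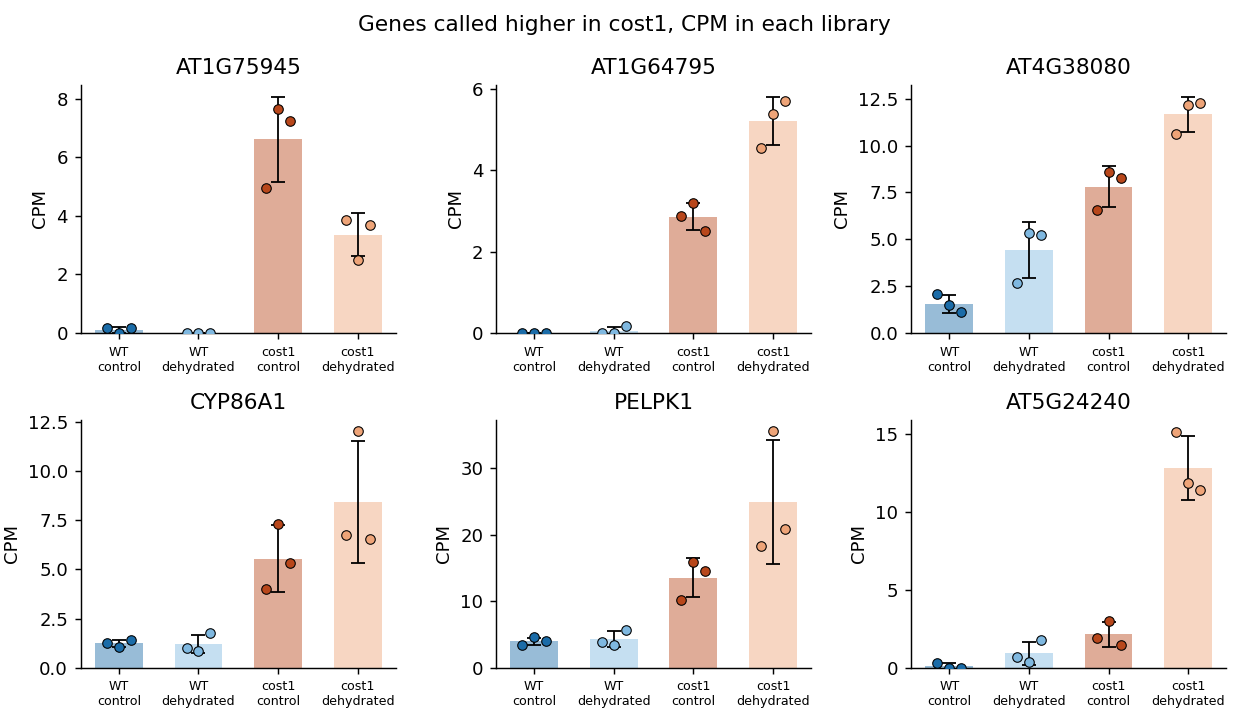
CPM (y axes) of 6 genes called higher in cost1, in control, under dehydration or both, in the 4 groups (x axes). Bars are means, error bars the SD of 3 libraries and points the single libraries; AT5G24240 averages 12.8 in cost1 dehydrated and 0.923 in WT dehydrated.

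Lists that passed the test under dehydration again had no called member. Autophagy genes had positive changes in 37 of 44 with a median of 0.13 (0 adjusted over the list alone, adjusted p = 0.000329), and unfolded protein response genes in 10 of 10 with a median of 0.20 (0 adjusted over the list alone, adjusted p = 0.00365). Dehydration- and ABA-induced genes had a median of 0.44 (0 adjusted over the list alone, adjusted p = 0.000617), salicylate and defence genes 0.45 (0 adjusted over the list alone, adjusted p = 0.0115) and glucosinolate synthesis −0.44 (1 lower adjusted over the list alone, adjusted p = 0.00446). These 5 lists had adjusted p = 0.748 with an estimated correlation. Cell cycle and DNA replication genes had negative changes in 19 of 23 with a median of −0.39 (0 adjusted over the list alone, adjusted p = 7.24e-06), seed storage and embryo markers a median of 2.35 (2 higher adjusted over the list alone, adjusted p = 7.61e-05) and senescence and dark-induced genes 0.31 (1 higher adjusted over the list alone, adjusted p = 0.009). These 3 had adjusted p = 0.62 with an estimated correlation. Without cost1 dehydrated replicate 2, the library farthest out, autophagy genes were at 0.07 (adjusted p = 0.27), unfolded protein response genes at 0.16 (0.0629), dehydration- and ABA-induced genes at 0.04 (0.7), salicylate and defence genes at 0.13 (0.56), glucosinolate synthesis at −0.08 (0.498), seed storage and embryo markers at 1.29 (0.0629) and senescence and dark-induced genes at 0.16 (0.179). Without WT dehydrated replicate 1 glucosinolate synthesis was at 0.10 (0.876), and without WT dehydrated replicate 2 salicylate and defence genes were at 0.33 (0.0854) and unfolded protein response genes at 0.12 (0.0854). Lists called without 1 library numbered 2 (cost1 dehydrated replicate 2) to 14 (cost1 dehydrated replicate 1). Jasmonate genes, not called here (median −0.13, adjusted p = 0.208), were called without WT dehydrated replicate 1 (−0.42, 0.00146) or cost1 dehydrated replicate 2 (−0.47, 0.000575). Aquaporins (0.04 and 0.0102) and auxin response genes (0.0296 and 0.0175) were called without WT dehydrated replicate 1 or cost1 dehydrated replicate 3. DREB and CBF factors (0.0224) and circadian clock genes (0.012) were called without WT dehydrated replicate 2. Photosynthesis nuclear genes (1.76e-06 and 0.00142) and stomatal lineage and guard cell markers (0.0424 and 0.0205) were called without WT dehydrated replicate 3 or cost1 dehydrated replicate 1. Flavonoid and anthocyanin synthesis was called without WT dehydrated replicate 3 (0.00747) or cost1 dehydrated replicate 3 (0.00823). Clade A PP2C phosphatases (adjusted p = 0.0631) were called without cost1 control replicate 2 (0.0146), cost1 control replicate 3 (0.0368) or cost1 dehydrated replicate 1 (0.00142), and without scaling beyond the total (0.0487). ABA kinases and bZIP factors (0.0205), ABA synthesis and catabolism (0.0244) and the expansin list (−0.41, 0.0241, against 0.12 with all libraries) were called without cost1 dehydrated replicate 1. By fry no list passed (lowest adjusted p = 0.393).

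The interaction asked whether dehydration moved genes differently in cost1. No gene was called by edgeR or limma-voom and 1 by DESeq2; 690 genes had an unadjusted p under 0.05, against 940 by chance. The smallest p among autophagy genes was that of VTI12, at 0.71 (SE 0.23, adjusted p = 0.999), and COST1 stood at 0.62 (SE 0.24, adjusted p = 0.999). In 7 lists the genes shifted together by the list test, with no called member and 0 adjusted over the list alone in each. Autophagy genes had positive changes in 36 of 44 (median 0.23, adjusted p = 1.26e-05) and flavonoid and anthocyanin synthesis negative ones in 14 of 15 (median −1.35, adjusted p = 0.000106). Glucosinolate synthesis had negative changes in 13 of 13 (median −0.59, adjusted p = 0.000281), cell cycle and DNA replication genes in 21 of 23 (median −0.34, adjusted p = 0.000174), jasmonate genes in 17 of 19 (median −0.56, adjusted p = 0.00126) and photosynthesis nuclear genes in 28 of 29 (median −0.28, adjusted p = 0.0291). These 6 lists had adjusted p = 0.801 with an estimated correlation. Senescence and dark-induced genes had positive changes in 12 of 15 (median 0.55, adjusted p = 0.00126, and adjusted p = 0.518 with an estimated correlation). Without cost1 control replicate 2, flavonoid and anthocyanin synthesis was at −0.19 (0.714), jasmonate genes at −0.12 (0.411) and photosynthesis nuclear genes at −0.03 (0.997), while autophagy genes were at 0.23 (0.000134). Without cost1 dehydrated replicate 2, the library farthest out, autophagy genes were at 0.11 (0.0263) and glucosinolate synthesis at −0.39 (0.0688), and glucosinolate synthesis was at −0.20 (0.292) without WT dehydrated replicate 1. Jasmonate genes were not called without WT dehydrated replicate 3 (−0.33, 0.119) or cost1 dehydrated replicate 1 (−0.31, 0.475). Photosynthesis nuclear genes were also not called without WT control replicate 2 (0.163), WT control replicate 3 (0.0783), WT dehydrated replicate 1 (0.537), WT dehydrated replicate 2 (0.379), cost1 dehydrated replicate 2 (0.146) or cost1 dehydrated replicate 3 (0.319). Other lists were called only with a library left out. Salicylate and defence genes were called without cost1 control replicate 2 (0.70, 8.58e-07), WT control replicate 2 (0.38, 0.00673) or cost1 dehydrated replicate 3 (0.38, 0.00939). Dehydration- and ABA-induced genes were called without cost1 dehydrated replicate 2 (−0.66, 0.00217) and cost1 dehydrated replicate 1 (0.16, 0.0134). Circadian clock genes were called without WT control replicate 3 (0.028), WT dehydrated replicate 2 (0.001), cost1 control replicate 3 (0.0246) or cost1 dehydrated replicate 2 (0.0354). Clade A PP2C phosphatases were called without cost1 control replicate 1 (0.0262), cost1 control replicate 3 (0.00724) or cost1 dehydrated replicate 2 (0.0106). Seed storage and embryo markers were called without cost1 control replicate 1 (−2.22, 0.0113). ABA kinases and bZIP factors (0.0395) and the expansin list (0.00529) were called without cost1 dehydrated replicate 1, and ABA synthesis and catabolism (0.04) and nitrate uptake and assimilation (0.04) without cost1 dehydrated replicate 2. By fry no list passed in the interaction (lowest adjusted p = 0.843).

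**Figure D5:**
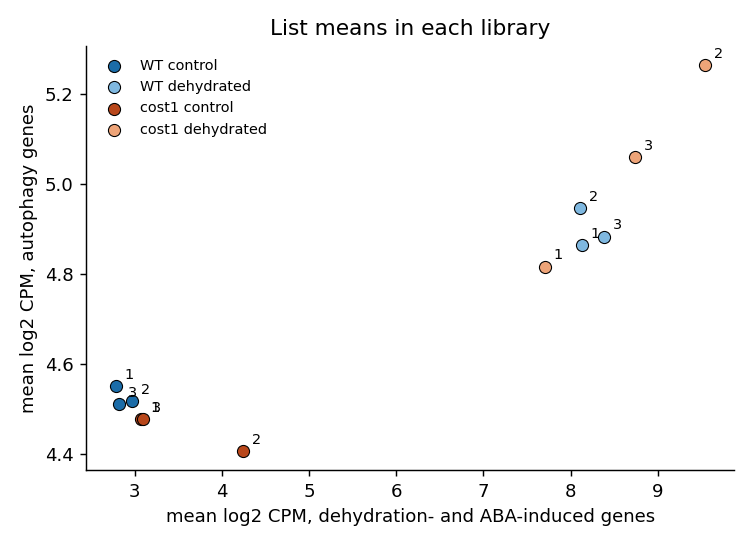
Mean log2 CPM of the 44 measured autophagy genes (y axis) against that of the 24 measured dehydration- and ABA-induced genes (x axis) in each of 12 libraries, coloured by group and numbered by replicate. Cost1 dehydrated replicates 2 and 3, at 5.26 and 5.06, lie above the WT dehydrated libraries at 4.86 to 4.95, and cost1 dehydrated replicate 1 lies below them at 4.82.

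The genotype difference in control was also compared with the dehydration response across the 18809 genes, to see whether the mutant had moved toward the dehydrated state. AT4G38080, which rose by 1.49 (SE 0.32, adjusted p = 0.00259) in WT, was called higher in both and no gene lower in both, against 0.746 and 0.206 for independent lists. The covariance with the WT response was 0.272, where the shared WT control libraries alone gave 0.044 in 20 simulations (0.0417 to 0.0465). The correlation was 0.431 and the simulated one 0.498, but these cannot be compared, since the simulated libraries had no dehydration response. With the mean of both responses, which the sharing does not inflate in the simulations, the covariance was 0.197 (correlation 0.327) against 4.23e-05. Without cost1 control replicate 2 these fell to 0.0746 with the WT response and 0.00298 with the mean response, so most of the covariance came from 1 library. The remainder still lay above simulations without that library, at 0.0423 to 0.0477 and −0.0145 to −0.0100. Genes were drawn independently there, so these ranges hold no deviation shared by the genes of a sample and cannot show a genotype effect.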

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

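Tests on other groupings of the libraries, on the dehydration level of autophagy genes and on phased output genes were set before their results were seen, the last on genes chosen after the clock genes had been looked at; the tests of dehydrated RNA in 1 library, of the mutation, of root tissue, of seed residue, of cost1 control replicate 2 for the autophagy list and of groupings that keep the replicate numbers together were chosen after. For 7 lists the dehydration response differed between the genotypes by the list test at the preset correlation, while none did with an estimated correlation or by fry. The estimated correlation decides little here, since it left even the dehydration- and ABA-induced genes uncalled in the WT response (adjusted p = 0.131). Calls at the preset correlation arose readily from other groupings: of 100 groupings by genotype labels moved within treatment, the real one included, 74 gave at least 7 lists, up to 17, so chance is not excluded for that number. These moved labels in each treatment separately and so broke the same-numbered cost1 pairs. The 10 groupings that keep each genotype's control and dehydrated library of 1 number together are too few for a share under 0.05; the other 9 gave 2 to 8 lists and up to 1 gene.

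Autophagy genes had a median interaction of 0.2339, and 3 explanations were weighed. Cost1 control replicate 2 as the source is argued against, since without it the adjusted p was 0.000134, although without cost1 dehydrated replicate 2 the median was 0.11 (adjusted p = 0.0263). Stronger dehydration of the sampled cost1 seedlings stays open, with values on both sides. Among the dehydrated libraries the genotype difference in the list mean fell by 71.55% when the mean of the dehydration- and ABA-induced genes was added as a covariate, from 0.149 to 0.0424 log2 (exact two-sided permutation p of the difference = 0.4, where the smallest possible is 0.1). Under dehydration 23 of 24 dehydration- and ABA-induced genes had a positive genotype change, with a median of 0.44. The list test gave adjusted p = 0.000617 at the preset correlation and 0.748 with an estimated one. Without cost1 dehydrated replicate 2 the median was 0.04 (adjusted p = 0.7). Yet the dehydration- and ABA-induced genes as a list were not shown to respond more in cost1: their median interaction was −0.108, with 12 positive and 12 negative changes (adjusted p = 0.723), and 0.231 without cost1 control replicate 2 (adjusted p = 0.206). Chance is not excluded either: of the 100 groupings, the real one included, 8 gave a mean interaction as large as the real 0.229 in either direction, up to 0.298. Among the 10 that keep the numbers together, the largest other was 0.289. A direct effect of the mutation on autophagy genes stays open, and 1 of 3 cost1 dehydrated libraries, replicate 1, was below every WT dehydrated library.

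The photosynthesis nuclear genes had a median interaction of −0.2806. The jasmonate genes had a median of −0.5613. Senescence and dark-induced genes had 0.5513, cell cycle and DNA replication genes −0.3375, glucosinolate synthesis −0.595, and flavonoid and anthocyanin synthesis −1.3519.

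Cost1 control replicate 2 lay apart from the other control libraries, with values shifted toward the dehydrated ones. RNA from dehydrated seedlings is argued against as the whole source, since 73 of 4072 genes that dehydration did not move in WT lay at least 2-fold from the other controls, against at most 7 in any other control library. The mutation stays open as a source. Without this library the covariance with the mean dehydration response was 0.00298, far under the 0.197 with it, but that restates that the pattern lies mostly in 1 library. The 0.00298 is above the −0.0145 to −0.0100 of simulations without a genotype effect, but these drew genes independently and cannot decide the question. Harvest at another time of day may have contributed and stays open: 15 of 16 circadian clock genes lay outside the other controls, a value seen before the test, and of 11 phased output genes 7 lay outside in 1 phase direction and 4 in the opposite one. Another control library also reached 7, but against a smaller set without cost1 control replicate 2, whose range is easier to leave. Another stress or handling of that sample was not tested.

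Other groupings of the libraries were counted for every comparison. The 10 splits of 3 libraries against 3 are too few for a share under 0.05. Every other split sets 2 libraries of 1 group with 1 of the other, so part of a real difference stays in it. That mixing also widens the spread within its groups. Where the groups differ widely, as in the dehydration responses, counts from other splits are thus no measure of chance. The real split and the highest other gave 8549 and 0 genes in the WT response, 9585 and 1 in the cost1 response, 4 and 0 in the genotype difference in control and 7 and 38 in that under dehydration. As many genes as the real split were reached by 1, 1, 1 and 2 of the 10 splits. The split with 38 genes set WT dehydrated replicates 1 and 3 and cost1 dehydrated replicate 1 against the rest. Across genotypes, deviations from the group means correlated at 0.3858 between the dehydrated replicates 1. They correlated at 0.3907 between WT dehydrated replicate 2 and cost1 dehydrated replicate 3, and at 0.2878 between WT dehydrated replicate 3 and cost1 dehydrated replicate 2. The other such pairs ran from −0.258 to −0.0598. Dehydrated samples of the genotypes thus shared deviations, and what lay behind these was not tested. In the cost1 response, where the numbers were taken as paired, the 3 other splits that part every pair gave 0 genes and 12, 13 and 16 lists. For lists the real and highest other numbers were 18 and 16, 17 and 17, 5 and 12, and 8 and 16, with 1, 2, 10 and 7 of 10 splits reaching the real number. The covariance with the mean response was 0.197 in the real split and 0.193 in the highest other, reached by 1 of 10. For the interaction all 100 groupings gave at least the real 0 genes, up to 15.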

How the results depend on the processing

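The lists with libraries left out were added after the data were seen; the other alternatives were planned. The dehydration responses kept their counts within 1.5 times under every alternative but a 2-fold limit, which left 4463 genes in WT and 4732 in cost1 by its own construction; leaving out 1 library gave 6766 to 9107 and 7608 to 10198. The genotype difference in control gave 15 genes by DESeq2, 1 with the strict filter, which tests fewer genes, 2 with the compared groups only, 1 with the replicate block and 1 to 7 with 1 library left out. Under dehydration these were 29, 4, 0, 2 and 0 to 8, and the interaction gave 1 by DESeq2 and 0 to 0 with 1 library left out. The covariance with the WT response was 0.357 by DESeq2, 0.426 without a filter and 0.0746 to 0.354 with 1 library left out, and with the mean response 0.00298 to 0.244. With an estimated correlation 0 lists were called in each of the 5 comparisons; with 1 library left out the lists called numbered 16 to 19, 16 to 20, 3 to 9, 2 to 14 and 5 to 10. With 1 library left out the median of 40 of 130 list results changed sign. Of these 2 were called with all libraries, jasmonate genes in control (−0.0407 to 0.557) and glucosinolate synthesis under dehydration (up to 0.0975). Another 3 were called with the other sign, salicylate and defence genes in control (−0.359 to 0.573), the expansin list under dehydration (−0.411) and dehydration- and ABA-induced genes in the interaction (0.157, in a range of −0.658 to 0.231). The test of seed storage and embryo markers in the interaction turned at a median of −2.22, in a range of −2.26 to 1.58. No named gene changed sign where it was called with all libraries or under the alternative. Sign changes of named genes called in neither were not counted. In the cost1 response, the 1 comparison whose numbers were taken as paired, the replicate block gave 9343 genes, 9126 of them among the 9585, and changed no call of a named gene or list beyond those given. That block was common to all 12 libraries, although same-numbered WT control and dehydrated libraries correlated at only 0.0426, 0.0104 and 0.0254. No fit paired the cost1 libraries alone, so the response with pairs inside cost1 is not shown. The main fit used no pairing. Elsewhere samples share a number only: over all 18 same-numbered pairs the correlation ran from −0.181 to 0.386 (median 0.0021, others −0.00975), 6 of 12 libraries correlated best with their own number, and the block gave 8358 genes in WT. Unless construction is given, the cause was not tested. The simulation recovered 62 of 100 genes at 2-fold. It held many changed genes, which eases the adjusted p of each, and these averaged at least 5 CPM and were drawn independently. Its share therefore does not give the power for the genotype differences, where few genes were called.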

Other observations

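The lists of suberin and root-only genes and the tests on them were chosen after the result was seen, starting from the call of CYP86A1, and the root-only list left out SHR, SCR, PHT1;1 and WOX5 after their values were seen. Genes of suberin synthesis and export build the lipid barrier of root endodermis, periderm and wounds. Their mean lay higher in every cost1 library than in every WT library of its treatment, without a list test. The mean log2 CPM over 15 genes, with 0.5 CPM added to each value, was 2.07 ± 0.260 (SD, n = 3) in cost1 control and 1.27 ± 0.0955 in WT control, and 2.99 ± 0.344 against 1.80 ± 0.186 under dehydration. Some of the genes lay near the floor: FAR4, GPAT7 and MYB41 were under 0.5 CPM in every WT library. Of 12 genes tested, 10 had a positive genotype change in control, all but KCS20 and FAR1, and 12 under dehydration, with medians of 1.16 and 1.297. Of these 0 were called in control and 1, CYP86A1, under dehydration. GPAT5 stood at 3.11 in control and 2.91 under dehydration (adjusted p = 0.965 and 0.283), and ABCG6, a suberin transporter gene, at 1.84 under dehydration (adjusted p = 0.13). GPAT5 was near the floor in WT control, at 0 to 0.317 CPM, so its change there is poorly determined.

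A larger share of root tissue in the cost1 samples could raise such genes, and was weighed with 8 root-only genes, among them CASP1 and COBL9. It cannot be told apart from a change in suberin genes in either treatment, because those genes lay near the floor. In control they summed to 43 counts in cost1 and 54 in WT, a ratio of 0.793 with an upper 95% bound of 1.21, while CYP86A1 differed 4.38-fold. Under dehydration 23 against 8 counts gave a ratio of 2.87 with an upper bound of 7.42, beside a CYP86A1 difference of 6.88-fold. The root cell markers fixed beforehand showed no rise, with medians of 0.04 in control and −0.15 under dehydration, PHT1;1 at 0.19 (SE 0.29) and 0.12 (SE 0.41), SHR at 0.08 and −0.22, SCR at 0.00 and −0.07 and WOX5 at −0.30 and −1.01. Of these SHR and SCR are expressed in shoots too, and WOX5 in control was near the floor. Seed residue, another candidate source, stays open: in the replicates 1, whose CRA1 of 3.03 and 3.70 CPM lay within the WT control range of 2.06 to 3.96, the suberin mean still exceeded the highest WT library of its treatment by at least 0.437, although 3.70 is above the WT dehydrated libraries at 0.172 to 1.75. A raised suberin programme in cost1 remains a hypothesis found and tested on the same libraries.

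Seed storage transcripts were uneven within cost1: CRA1, a cruciferin gene, was at 170 CPM in cost1 control replicate 3 and 17.5 in cost1 control replicate 2, and CRC at 114 and 16.2. GRP7, an evening-phased RNA-binding protein gene, was at 308 CPM in cost1 control replicate 2 and 990 to 1323 in the other controls, and CCA1, a morning clock gene, at 173 against 60.5 to 85.2.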
